A study of Mus musculus with 4 samples.

How the data were processed

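RNA was sequenced from neural precursors that had been derived from A2lox mouse embryonic stem cells, a line built for doxycycline-inducible expression. Per the labels, the cells carried an inducible knockdown of Geminin, grew as a monolayer in N2B27 (a serum-free medium for neural differentiation), received 500 ng doxycycline from day 3 and were harvested on day 5. The 4 libraries fall into 2 groups, 3 Geminin knockdown libraries from independent experiments and 1 control library grown without doxycycline, and per the labels the 4 shared 1 lane of an Illumina HiSeq2000. They are called knockdown libraries 1, 2 and 3 and the control. No culture with doxycycline but without the knockdown construct was used here, so doxycycline and Geminin knockdown cannot be separated in any comparison.

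The submitters' processing notes name TopHat for alignment, Cufflinks and Cuffdiff for quantification, and mm9 as the genome build. Versions and the gene annotation are not given in the sources used here. Per the file headers, each of 3 deposited tables compares 1 knockdown library with the control, so the 3 tables share their control. Each table holds 21690 features with unique symbols. The authors gave FPKM for both libraries, that is, fragments scaled to exon length and to the mapped fragments of the library. The deposited tables also hold a Cuffdiff p-value, a q-value, which exceeds 1 in places and was treated as a score, and the natural log of control over knockdown, a score used here to check the direction of the columns. The deposited mark of significance corresponds to a q-value under 0.05 with a usable test status. Each Cuffdiff test sets 1 library against 1 library, so it compares those libraries and not the conditions. The 2 deposited files that repeat the marked features were not used. Control values were equal within 0.1% in 90.7% to 91.2% of features between tables, so ratios were always formed within a table.

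Counts are not given, and absolute depth is unknown. Features too low for a test changed in steps of whole reads. The ratio of 1 read in a knockdown library to 1 read in the control was 0.997, 0.867 and 1.029 in libraries 1, 2 and 3, and 78.9% to 82.9% of the low ratios lay within 0.2% of a ratio of whole reads up to 12. This gives depths of 1.00, 1.15 and 0.972 relative to the control. FPKM values are not counts, and no count model was used. Values listed as exactly 0 can be failed estimates, particularly in features shorter than the sequenced fragments, and they are described as listed at 0.

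Following the design stated for the series, a feature was called when the authors' deposited tables marked it significant in at least 2 of the 3 tables, in 1 direction and with no significant mark in the opposite direction. This is named the study's rule below. Of the 21690 features, 14477 had usable tests in enough tables to be called. Counts of gene list members below are over measured members, and those that could not be called count as not called. Separately, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a trended prior variance, on 11968 features with usable values in all 3 tables and a mean FPKM of at least 1. Each knockdown value was placed on the control's scale by its own table. The fit has 2 residual degrees of freedom, all from the knockdown libraries, and assumes that the lone control varies as they do. Where the control value of a feature differed between tables, that difference also entered the spread. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 ratios are on the log2(FPKM + 1) scale and understate changes of low genes. An exact permutation test of 3 libraries against 1 cannot give a p below 0.25 one-sided or 0.5 two-sided, so none was run.

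Genes were named by a rule fixed before the data were examined. It takes Gmnn with Cdt1, Mcidas and Smarca4. It adds the 12 features that rose most and the 12 that fell most among those meeting the study's rule with a mean FPKM of at least 1 and the same sign in every knockdown library. From each of 29 gene lists it takes up to 4 called members with the largest mean log2 ratio, or the 2 most abundant members where none was called. Mcidas was matched to its older symbol in the tables. Some genes that the rule names are not reported here. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation and with fry. The estimated correlation had a median of 0.227 over lists, far from the preset value. It was 0.873 for the epithelial, 0.665 for the neuronal and 0.653 for the pluripotency list. With it, the adjustment gave many lists the same adjusted p, although their unadjusted p differed. Both this version and fry rest on the 2 residual degrees of freedom, so they had little power. The correlation alone does not account for lost calls: the replication licensing list lost its call with an estimated correlation of -0.0234. Fisher's exact test on called members, per direction and against the 14477 features that could be called, was added after seeing the data, as were a fold rule with each library as reference, counts without short RNA features and counts of list members without each knockdown library. Members of the list of mitochondrially encoded genes were not analysed here.

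The scripts were tested on simulated data. With 200 of 11968 features changed in 5 runs per size, limma recovered 0% of changes of 1 log2 unit, 77.0% of changes of 2 units and 94.5% of changes of 3 units. False calls averaged 0.4, 10.4 and 12.4 per run at these sizes. In 20 simulated runs without any change it called at most 5 features, and 2 runs had a list called. Chance similarity from the shared control was simulated in 100 runs of unchanged libraries, in 2 ways. Correlations, covariances and shared signs were simulated with the spread estimated by limma, which holds real differences between the knockdown libraries as well as noise. Calls and their overlap were simulated as standard normal test values that share a control, called at the largest p-value marked significant in each of the authors' tables, and these hold no differences between cultures beyond what the Cuffdiff test assumes. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used. Alternatives covered the number of tables, thresholds, pseudocounts, filters, scaling, prior variance, the kind of set test and leaving out each knockdown library. Coordinates are those of the deposited tables on mm9.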

Results

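Expression was measured in 3 Geminin knockdown libraries and 1 control library of neural precursors made from mouse embryonic stem cells. The question the design poses is which transcripts change when Geminin, a small nucleoprotein that inhibits the replication licensing factor Cdt1, is reduced during neural differentiation. The knockdown libraries come from independent experiments, while the control has no replicate, so no spread between control cultures is known. Depth relative to the control was 1.00, 1.15 and 0.972 in knockdown libraries 1, 2 and 3.

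Gmnn, which encodes Geminin and lies on chromosome 13 from 24843713 to 24853806 (mm9), was lower in every knockdown library. Its FPKM was 27.0, 65.9 and 27.9 in libraries 1, 2 and 3, against 113 in the control. The level left was 35.7% ± 19.7 (SD, n = 3) of the control, and 24.0%, 58.4% and 24.7% in the single libraries. The authors' deposited tables marked the fall as significant in libraries 1 and 3, but not in library 2. In limma the log2 change was -1.59 with a standard error of 0.56 and did not pass the threshold (adjusted p = 0.999). Cdt1, the binding partner of Geminin, had 44.5 ± 4.87 FPKM (SD, n = 3) against 46.1 in the control. Smarca4, the catalytic subunit of SWI/SNF complexes, had 96.6 ± 7.95 (SD, n = 3) against 103. Neither was called. Mcidas, a Geminin relative, was listed at 0 in all 4 libraries.

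**Figure D1:**
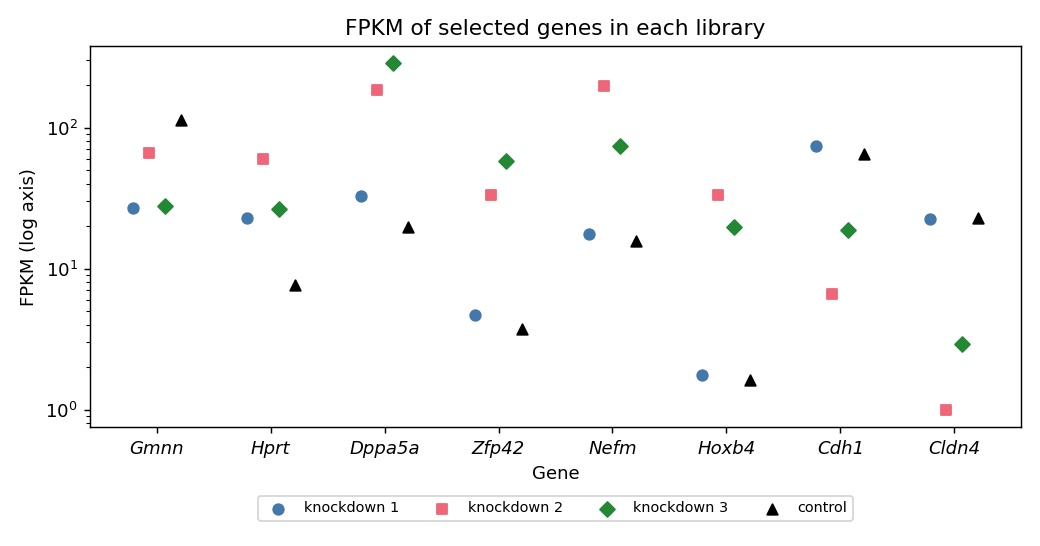
FPKM of 8 named genes (x axis) on a log axis (y axis), with 1 point per library for the 3 knockdown libraries and the control. Gmnn is below the control value of 113 in each knockdown library, while Nefm is at 17.6 in knockdown library 1, close to the control's 15.6, and at 198 and 74.2 in libraries 2 and 3.

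By the study's rule 286 features rose and 131 fell. Most of these calls came from the same 2 libraries: 370 of the 417 were significant against the control in knockdown libraries 2 and 3 only, and 47 involved library 1. Among features that rose, the median log2 ratio was 0.11 in library 1, 1.51 in library 2 and 1.43 in library 3. Among those that fell it was -0.08, -1.33 and -1.14. Without knockdown library 1, 272 rose and 120 fell. Without library 2 the counts were 12 and 23, and without library 3 they were 12 and 22. With a library left out, both remaining tables had to mark a feature. The 370 features are therefore lost by construction without library 2 or without library 3. The same holds for list members called in these libraries only, so the list counts below are no test of robustness. Camera with an estimated correlation rests on 2 residual degrees of freedom and had little power. A list that it did not call below was therefore not shown to be unchanged. A further 37 features were significant in at least 2 tables with opposite directions and were not called. Because the tables share 1 control, chance calls recur between them. Simulated unchanged libraries gave on average 3.82 calls and at most 8 over the 14065 features usable in every table, of which 234 rose and 129 fell by the study's rule. That simulation holds no differences between cultures beyond what the Cuffdiff test assumes. With each library in turn as the shared reference, a choice made after seeing the data, a fold rule of at least 1 log2 unit in at least 2 of the 3 others gave 361 features for the control, and 384, 528 and 439 for knockdown libraries 1, 2 and 3. The calls therefore cannot be assigned to the knockdown on their number.

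The features that rose most included genes of the 2-cell embryo and of pluripotent cells. Zscan4f, a zinc finger gene expressed in 2-cell embryos, had 1.00, 13.8 and 27.1 FPKM in libraries 1, 2 and 3, against 0.210 in the control. Zscan4b, Zscan4c, Zscan4d and Zscan4e also rose, as did Tcstv1, Tcstv3 and the predicted gene Gm4340. The members of these families are near-identical copies that share reads, so the level of each is uncertain. Dppa5a, a marker of pluripotent cells, had 32.8, 184 and 286 FPKM against 19.9. Nanogpd rose too and overlaps Nanog, so their reads cannot be told apart. Nhlh2, a neuronal transcription factor, had 0.194, 26.7 and 10.2 against 0.146. Abhd1 was one of 3 features higher in every table, with 25.2, 17.2 and 5.85 against 1.25, and it overlaps Preb.

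Among the 12 features that fell most, Gmnn itself was the only one of the rule's starting genes. Cldn4, a tight junction claudin, had 22.3, 0.991 and 2.94 FPKM in libraries 1, 2 and 3 against 22.7 in the control. Cyp26b1, which degrades retinoic acid, had 6.67, 0.645 and 1.08 against 9.73. Vgll3 had 28.3, 5.14 and 5.39 against 32.5, and Rln1 had a mean of 57.8 ± 52.0 (SD, n = 3) against 142. Tnnc1, Thsd4 and Cntnap2 fell as well. Mir669k, Snord85 and Snord45c were also among them, but these short RNA features lie within other genes and were listed at 0 in at least 1 knockdown library.

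The features called in all 3 tables numbered 3 that rose and 14 that fell. At 10 to 100 FPKM in the control, the median standard error implied by the Cuffdiff test was 0.082, 0.186 and 0.173 natural log units in libraries 1, 2 and 3. A mark in library 1 can therefore stand for a small change. Lin28a was at 92.2% and Peg10 at 92.3% of the control there, while Hprt was at 297%. Hprt, a purine salvage enzyme on chromosome X from 50341254 to 50374837, had 22.7, 60.1 and 26.3 FPKM against 7.62, and the mean was 36.3 ± 20.6 (SD, n = 3). Tor1aip2 rose while Tor1aip1, listed at the same position, fell, and both levels are uncertain because the genes overlap. Lin28a, an RNA-binding protein of early embryonic cells, had 423, 169 and 193 FPKM against 459. Peg10 had 232, 78.0 and 123 against 251, and Fzd7, a Wnt receptor, had 66.8, 51.8 and 38.3 against 82.1. These 17 were counted without regard to level, and Nme3 and Traf3ip3 among them were below 1 FPKM in every library.

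Neuronal genes formed the list with the most calls. Of 47 measured members 20 rose, 1 fell and 26 were not called. Nefm, a neurofilament subunit, had a mean of 96.7 ± 92.5 FPKM (SD, n = 3) against 15.6 in the control. Robo3, an axon guidance receptor, had 0.101, 14.5 and 6.50 FPKM against 0.203, and Nhlh1 had 0.334, 13.2 and 5.80 against 0.470. The median log2 ratio of tested members was 0.08, 1.57 and 0.79 in libraries 1, 2 and 3. Without library 2, or without library 3, 0 members were called. By camera the list was higher (adjusted p = 4.4e-05), with adjusted p = 0.722 with an estimated correlation.

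Of 31 pluripotency genes 14 rose, 1 fell and 16 were not called. Dppa5a, Zfp42, Tdgf1 and Esrrb had the largest mean ratios. Zfp42 had 4.68, 33.0 and 58.0 FPKM against 3.74, and Esrrb had 0.415, 6.83 and 12.6 against 0.417. Lin28a was the member that fell. Median log2 ratios were 0.10, 0.74 and 1.48 in libraries 1, 2 and 3, and the count of members that rose was 1 without library 2 and 0 without library 3. Fibroblast markers, a list for the feeder cells, had medians of 0.03, 0.11 and 0.52 in the same libraries. For the pluripotency list, camera gave an adjusted p = 6.4e-06, and adjusted p = 0.722 with an estimated correlation. Of 19 germline and 2-cell genes 8 rose and 0 fell, Zscan4c, Zscan4d, Tcstv1 and Tcstv3 among them. Without library 2, or without library 3, 0 were called. Camera tested 5 other members of the list, not these 4 genes, so its result is no test of them (adjusted p = 0.048, and adjusted p = 0.722 with an estimated correlation). That call was lost without library 1 (adjusted p = 0.074), without library 3 (adjusted p = 0.0995) and with a pseudocount of 0.1 (adjusted p = 0.0597). Of 15 primed epiblast genes 4 fell and 0 rose: Wnt8a, Pou3f1, Cldn6 and Dnmt3b, and 0 were called without library 2 or without library 3. That list was not called by camera (adjusted p = 0.25), but it was without library 1 at the preset correlation (adjusted p = 0.0045). With all libraries it had adjusted p = 0.722 with an estimated correlation, which was not run without library 1.

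Of 28 measured epithelial genes 10 fell and 0 rose, and median log2 ratios were 0.10, -2.19 and -1.36 in libraries 1, 2 and 3. Cdh1, which encodes E-cadherin, had 74.2, 6.63 and 18.8 FPKM against 65.2. Cldn7 had 8.20, 0.421 and 0.931 against 7.63, and Esrp1, an epithelial splicing regulator, had 5.76, 0.617 and 0.560 against 6.36. Camera placed the list lower (adjusted p = 7.7e-05), with adjusted p = 0.722 with an estimated correlation. The members called were all called in libraries 2 and 3 only, so by construction none remained without library 2 or without library 3.

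Homeobox genes of the Hox clusters, which pattern the body axis, rose in 8 of 28 measured members and fell in 0. Of the 28, 16 could be called. Hoxb4 had 1.75, 33.1 and 19.6 FPKM against 1.62, and Hoxc4 had a mean of 9.45 ± 7.84 (SD, n = 3) against 0.775. Hoxd3 and Hoxb7 also rose, and Hoxd3 overlaps Hoxd4. No Hox member was called without library 2 or without library 3. Camera gave an adjusted p = 0.043, and adjusted p = 0.722 with an estimated correlation. The call was lost without library 2 (adjusted p = 0.062) and without library 3 (adjusted p = 0.081). Among 45 genes of neural precursor identity 4 rose and 3 fell. Without library 2, or without library 3, 0 rose and 1 fell. Pou3f3 had 6.30, 54.9 and 29.9 FPKM against 7.18, whereas Lix1 and Pou3f1 were among those that fell. That list was not called by camera (adjusted p = 0.41). In the Notch list 5 of 24 members rose and 0 fell, with Dll3, a Notch ligand, at 0.935, 12.8 and 8.13 FPKM against 0.782, and with Hes6, Nrarp and Dner among the others, and 0 rose without library 2 or without library 3. Camera gave an adjusted p = 0.042, and adjusted p = 0.722 with an estimated correlation. It lost the call without library 2 (adjusted p = 0.10) and without library 3 (adjusted p = 0.11).

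**Figure D2:**
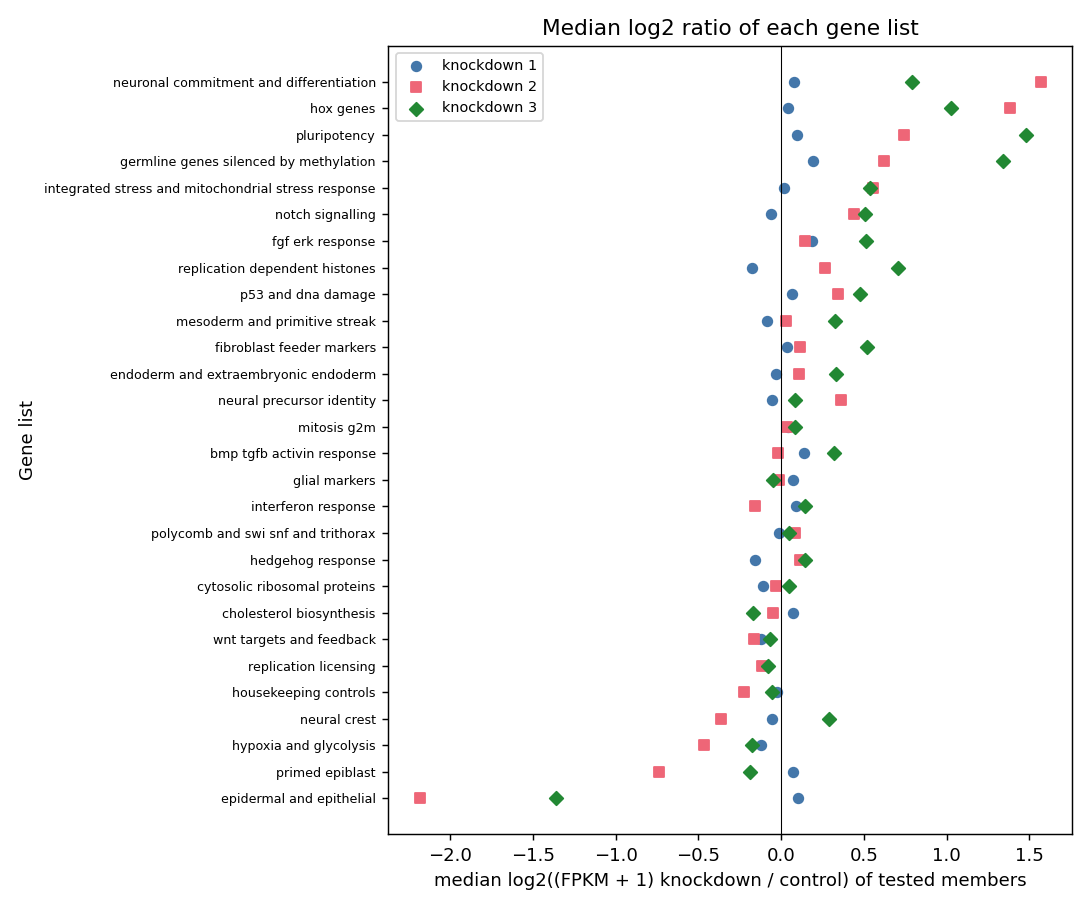
Median log2((FPKM + 1) knockdown / control) of tested members (x axis) for each list with at least 5 tested members (y axis), with 1 point per knockdown library. For the epithelial list the medians are 0.10, -2.19 and -1.36 in libraries 1, 2 and 3, and for the neuronal list 0.08, 1.57 and 0.79.

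Of 32 genes of the integrated and mitochondrial stress responses 9 rose and 0 fell. Chac1, which degrades glutathione, had 5.49, 17.0 and 17.0 FPKM against 3.15, and Asns, asparagine synthetase, had 111, 199 and 206 against 104. Nupr1 and Atf5 also rose. Median log2 ratios of the list were 0.02, 0.56 and 0.54 in libraries 1, 2 and 3, and 0 members were called without library 2 or without library 3. Camera gave an adjusted p = 2.3e-05, and adjusted p = 0.722 with an estimated correlation. Of 27 p53 target genes Cdkn1a, Sesn2 and Trp53i11 rose and 0 fell (camera adjusted p = 0.0037, and adjusted p = 0.722 with an estimated correlation). Without library 3 the p53 list was not called by camera (adjusted p = 0.051), and 0 of its members met the study's rule without library 2 or without library 3. Of 26 genes of hypoxia and glycolysis 4 fell, Ldha, Slc2a3, Pfkl and Pkm2, and 0 rose (camera adjusted p = 0.0025, and adjusted p = 0.722 with an estimated correlation). The count was 2 without library 1, 2 without library 2 and 4 without library 3.

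For replication licensing, the process Geminin restrains, 1 of 38 measured members was called, and 0 were without library 2 or without library 3. Gins2 had a mean of 28.7 ± 31.8 FPKM (SD, n = 3) against 55.7, with 63.9 in library 1 and 2.15 in library 3, and it overlaps Gse1. The median log2 ratio was -0.09, -0.12 and -0.08 in libraries 1, 2 and 3. Camera placed the list lower (adjusted p = 0.0095), with adjusted p = 0.722 with an estimated correlation. None of 34 mitosis genes was called, and Top2a had 264 ± 19.0 FPKM (SD, n = 3) against 233. None of 24 replication-dependent histone genes met the study's rule. Their camera test was past the threshold (adjusted p = 0.042), with adjusted p = 0.722 with an estimated correlation. Without library 3 it was not (adjusted p = 0.90), with the direction reversed. Adjusted over the list alone, limma called 1 histone gene, Hist2h4, and 1 hedgehog gene, Nkx6-2, against 0 in both lists over all features tested. These genes are outside the naming rule and were named after their values were seen. Each of 28 lists was adjusted separately with no correction over lists, so such calls can arise by chance.

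In the remaining lists few members were called, and most of these calls needed both library 2 and library 3. Without library 2, or without library 3, 0 members were called in the fibroblast, chromatin regulator, mesoderm, endoderm, glial, neural crest, Wnt and cholesterol synthesis lists. In the FGF list 1 member rose without library 2 and 0 without library 3, and in the BMP and activin list 0 fell without library 2 and 1 without library 3. In the FGF list Dusp4, Etv5, Etv1 and Il17rd rose, out of 20, and camera called the list without library 2 (adjusted p = 0.0018) but not with all libraries (adjusted p = 0.097, and adjusted p = 0.722 with an estimated correlation). Camera likewise called the BMP and activin list without library 2 (adjusted p = 0.0454), and the endoderm and cholesterol synthesis lists without library 1 (adjusted p = 0.0288 for both), and none of these with all libraries. With all libraries and an estimated correlation, adjusted p = 0.912 for the BMP and activin list and adjusted p = 0.722 for the endoderm and cholesterol synthesis lists. These calls are at the preset correlation, and the estimated one was not run with a library left out. Among 42 chromatin regulators of the Polycomb, SWI/SNF and Trithorax groups Bmi1 and Cbx7 rose. Postn, Lox and Col5a2 rose among 24 fibroblast markers, a list included because the stem cells had been kept on feeder fibroblasts, and camera gave an adjusted p = 0.043, and adjusted p = 0.722 with an estimated correlation. Without library 3 its adjusted p was 0.45. Called members numbered 2 each for mesoderm (Tcf15 and Wnt5a rose, of 36), endoderm (Cubn and Col4a1 rose, of 29), glia (Slc1a2 and Nfia rose, of 16) and the BMP and activin response (Id1 and Fst fell, of 28). Sfrp1 was the 1 of 24 Wnt genes that fell. In the neural crest list 1 of 25 members was called, and in the cholesterol synthesis list 1 of 23. Of 16 housekeeping genes Hprt rose and Tfrc fell, and without library 2 the counts were 2 and 0. No member was called among 29 interferon, 47 ribosomal protein and 15 hedgehog genes, of which 14, 47 and 11 could be called. In the interferon and housekeeping lists the median, the mean and the camera direction differed in sign, and neither was called by camera. Rps18 had 2980 ± 230 FPKM (SD, n = 3) against 3125.

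By limma, 3 features were higher and 12 lower in knockdown. All 15 were short RNA features, 11 microRNAs and 4 small nucleolar or Cajal body RNAs. Of these, 12 were listed at 0 in every knockdown library and 3 were listed at 0 in the control, and 0 met the study's rule. For the 12, the features' own spread in the fit came only from control values that differed between the deposited tables. Their p-values therefore hold no variation of these features between cultures. Variation between cultures entered them only through the prior variance, which is estimated from other features. Snora20 and Mir29b-2 had the smallest adjusted p, 0.00127. Among the features that are not short RNAs, 0 passed the limma threshold. Fewer of them had an unadjusted p under 0.05 than chance alone would give on average. Changes of 1 log2 unit were recovered in 0% of simulated cases, so limma could not be expected to detect changes of that size. The simulation gave a changed feature the same change in every knockdown library. Larger changes that differed between these libraries did not pass either. Gm4340 had a log2 change of 3.09 with a standard error of 1.73, and Dppa5a had 2.54 with a standard error of 1.26.

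Similarity between the 3 comparisons differed by pair. Across 11968 features, which are not independent replicates, Pearson's r of the log2 ratios was 0.310 for libraries 1 and 2, 0.354 for libraries 1 and 3, and 0.604 for libraries 2 and 3. Unchanged libraries simulated against a shared control gave 0.50, 0.495 and 0.496. The covariances were 0.163, 0.169 and 0.318, against 0.150, 0.149 and 0.148 simulated. Short RNA features weigh heavily on these values. With 165 of them left out, a choice made after seeing the data, r was 0.198, 0.233 and 0.740, and the covariances were 0.0258, 0.0282 and 0.161 against 0.0642, 0.0641 and 0.0641 simulated. The same sign was seen in 58.1%, 58.6% and 74.2% of features, against 66.6% in simulated pairs. Significant features shared in direction numbered 34, 35 and 392 for the 3 pairs, where simulation gave 1.17, 1.08 and 2.03, and those significant in opposite directions numbered 29, 11 and 7. Independent lists would share 3.65 higher and 4.47 lower features between libraries 1 and 2, which shared 12 and 22. For libraries 1 and 3 the values were 3.69 and 2.84 against 12 and 23 shared, and for libraries 2 and 3 they were 15.3 and 3.81 against 272 and 120 shared. Part of any excess may come from the single shared control. In a comparison not planned in advance, library 1 took the place of the control for the 370 features called in libraries 2 and 3 only. Both libraries kept the called direction in 366, with median absolute log2 ratios of 1.44 and 1.34, against 1.53 and 1.39 to the control. These values argue against the control alone as the source of these 370 calls, although no mark in library 1 was part of their selection. For pairs with library 1 the share of the control cannot be split.

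**Figure D3:**
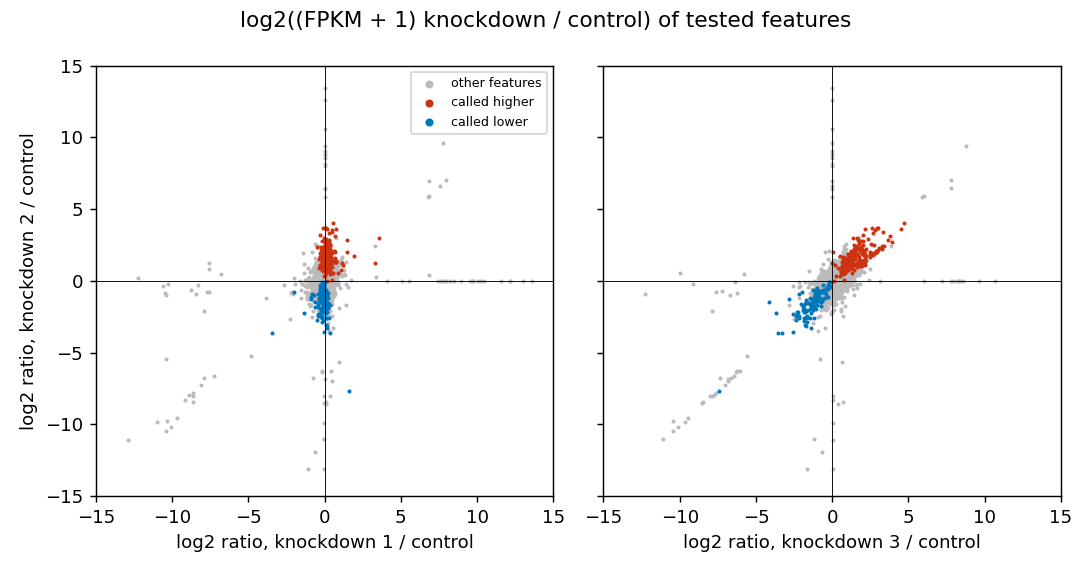
Log2((FPKM + 1) knockdown / control) of 11968 tested features in knockdown library 2 (y axis) against library 1 (left) and library 3 (right), with features called higher in red, called lower in blue and others in grey. Called features spread along the y axis in the left panel, with a median log2 ratio of 0.11 in library 1 for those that rose, and along the diagonal in the right panel, with medians of 1.51 and 1.43 in libraries 2 and 3.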

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

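Counts without short RNA features, counts of features usable in every table and Fisher's exact test were chosen after seeing the data. No paired analysis was possible because the control has 1 library and the groups share only replicate number 1. For each result with a range, the cause was not tested unless stated. The study's rule gave 286 higher and 131 lower features. Requiring all 3 tables left 3 and 14, and any 1 table gave 758 and 510, by construction. A q-value under 0.01 gave 161 higher, and a mean log2 ratio of at least 1 in size left 156 and 54. Leaving out 1 knockdown library, with both remaining tables required, gave 12 to 272 higher and 22 to 120 lower. Limma called 3 higher and 12 lower. Higher calls were 0 with pseudocount 5, 0 with no filter, 1 at a mean FPKM of at least 5 and 0 without a trend. Lower calls were 6 with pseudocount 0.1, 6 with pseudocount 5, 4 with no filter, 7 at a mean FPKM of at least 5 and 7 without a trend. Leaving out 1 library gave 1 to 4 higher and 5 to 24 lower. Of 12 lists called by camera, 0 were called with an estimated correlation and 0 by fry. Both of these versions rest on 2 residual degrees of freedom and had little power. Leaving out 1 library gave 6 to 14 lists, and Fisher's exact test called 13. The adjusted p of the histone list ranged from 0.00087 to 0.902 on leaving out 1 library, and its direction reversed without library 3. The Gmnn log2 ratio of -1.59 had its weakest value at -1.37 and kept its direction in all 5 alternatives. Counted once per gene and alternative, limma results of single named genes kept their side of the threshold in 1174 cases, lost it in 65 and gained it in 3. Only the 15 features called by limma could lose it, so the 1174 cases do not measure how stable the calls were. Depth in reads is unknown, which limits statements on low features.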

Other observations

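All tests of explanations in this part were chosen after the result was seen. Called members of the pluripotency and neuronal lists differed in their proportions between libraries 2 and 3, and no other pair of lists was compared. For called members of the pluripotency list, the excess over the control in library 3 was a median of 1.87 times that in library 2, and it was higher in library 3 for 14 of 14 members. Germline and 2-cell members had a median ratio of 1.86, with 8 of 8 higher in library 3. Neuronal members had a median ratio of 0.428, with 0 of 20 higher in library 3. Hox members had a median ratio of 0.598, with 3 of 8 higher in library 3, and stress response members 1.00, with 5 of 9. All called features that rose outside the pluripotency and neuronal lists, and that exceeded the control in both libraries, had a median ratio of 0.953, with 119 of 249 higher in library 3.

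Most calls came from knockdown libraries 2 and 3, while knockdown library 1 lay near the control. A weaker knockdown in library 1 is argued against by its Gmnn level, 24.0% of the control, the lowest of the 3, although protein was not analysed here. Exchanged labels of library 1 and the control are argued against by Gmnn in library 1 at 0.240 times the control. A difference between experiments, with the control nearer to library 1, stays open. Library 1 differed from the control by a median of 0.126 log2 units and library 2 from library 3 by 0.160. Both were below the smallest of the 4 other pairs at 0.195. The titles give the control and knockdown library 1 the same number, 1, but the labels do not state that they share an experiment. A varying response to the knockdown cannot be told apart from such a difference. Setting each library apart in turn, limma called 15 features for the control and up to 29 for another library, with an unadjusted p under 0.05 in 152 features for the control and 274, 750 and 604 for knockdown libraries 1, 2 and 3, and camera called 12 lists for the control and 8, 15 and 9 for those libraries; at least 15 calls came from 3 of the 4 choices, and 4 choices are too few for a share under 0.05.

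Hprt rose in every knockdown library. A rise of the whole chromosome region is argued against by its 5 expressed neighbours within 500 kb, whose median log2 ratio was at most -0.0782 in any library. A candidate explanation is transcription driven by doxycycline, since A2lox lines carry their inducible cassette next to Hprt. Its log2 ratio was 2.82 in library 2, the library with the most Gmnn left. Doxycycline and knockdown cannot be told apart, because each knockdown library received doxycycline and the control did not, so an effect of Geminin on Hprt also stays open.

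Pluripotency and neuronal genes rose together in libraries 2 and 3. A single source for both lists, with the same composition in both libraries, is argued against by their proportions. The lower quartile of the pluripotency excess ratio lay 1.70 log2 units above the upper quartile of the neuronal one. These quartiles are over genes and not cultures, so a common source whose composition differs between experiments stays open. Undifferentiated cells left in the cultures may have contributed to the pluripotency list. Its excess ratios had a quartile range of 0.28 log2 units against 1.16 for other called features, but the neuronal and stress lists were also narrow, at 0.44 and 0.42, so the test cannot separate such cells from regulation of the genes, and Cdh1, which stem cells express, fell to 6.63 and 18.8 FPKM from 65.2. Carried-over feeder fibroblasts were not tested as a source, and the medians of their list were 0.03, 0.11 and 0.52 log2 units in libraries 1, 2 and 3. An effect of Geminin on both lists stays open, but their medians did not follow the depth of the knockdown. Gmnn left was 24.0%, 58.4% and 24.7% of the control in libraries 1, 2 and 3. Neuronal medians were 0.08, 1.57 and 0.79 log2 units in these libraries, and pluripotency medians were 0.10, 0.74 and 1.48. Geminin protein was not analysed here.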
